A study of Mus musculus with 16 samples.

How the data were processed

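RNA from 16 samples of concanavalin A-injected mice was hybridised to Agilent mouse arrays of 1 design, labelled with Cy3 alone. The samples fall into 6 groups by the treatment and description labels: 4 groups of 3 livers and 2 groups of 2 samples of hepatic inflammatory cells. For the 2 untreated samples of inflammatory cells the source label also mentions the stem cell treatment, while their treatment and description labels do not. They were used as untreated, as the latter pair of labels has it.

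Each deposited scanner file holds spot intensity on a linear scale, made with Agilent Feature Extraction 10.5.1.1, per the file headers and the submitters' processing notes. Per the file headers, the background was subtracted and the signal was detrended across the array, with a surrogate value for spots not above background, and no normalization between arrays was applied. The authors' series value table holds the same intensity values: its largest difference from the processed signal of the scanner files was 0 on each of the 16 arrays, and the column medians ran from 24.0 to 42.3. Nothing in that table is centred or on a log scale, so using it in place of the scanner files changed no value. Probe positions are on genome build mm8, per the file headers.

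Every array held 43379 spots besides 1639 control spots, which were left out, and these spots carried 41174 probes. Spots well above background made up 52.1% to 62.5% of an array, the 75th percentile of the processed signal ran from 212 to 426, and 0 spots were saturated. The number of arrays limits the precision of every comparison. The main setting was log2 of the processed signal minus the array's own 75th percentile. Spots marked as non-uniform or population outliers (55 to 100 spots per array) were set to missing, and spots of 1 probe were averaged. A probe was kept when it was well above background on at least 3 of the 12 liver arrays, 2 of the 4 arrays of inflammatory cells, or 2 of the 16 arrays in the fit that holds both tissues.

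Probes were named from the design's symbols and accessions through the reference gene table. Of 41174 probes, 23374 were named by accession, 6733 by a current symbol and 2919 by an older symbol, 1662 kept the name in the design, and 6486 had no symbol and were left out of gene counts. For 4830 probes the accession gave another symbol than the design. A gene was represented by its kept probe with the highest mean over all arrays of the fit, chosen without regard to groups. Where the other probes of a named gene went the other way, the text says so. This left 14580 genes in the liver fit, 14182 in the fit of inflammatory cells and 16233 in the fit of both tissues.

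Groups were compared with limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 for the adjusted p. The 12 liver arrays shared 1 fit of 4 group means, the 4 arrays of inflammatory cells had a fit of their own, and comparisons across tissues used all 16 arrays. Every adjusted p of a gene is from these limma fits, and every error after ± on a log2 change is the standard error of the fit. A gene not well above background on any array of a group has only a bound there. Its change is then given as at least so many fold: the brighter group's mean over the dimmer group's mean of, on each array, the higher of the gene's own signal and the lowest signal of any spot well above background. For a difference of effects, the fitted value is followed, where groups lie below background, by the difference with signals under that floor raised to it, which has no test.

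The 22 gene lists, the rule for the genes named and the first set of other settings were fixed before the data were examined. The lists cover the interferon-gamma response, the type I interferon response, T cell cytokines and activation, myeloid inflammatory cytokines and NF-kB targets, chemokines, acute phase proteins, hepatic metabolism and cytochrome P450, immediate early genes, heat shock and the unfolded protein response, cell death, the cell cycle and stromal cell immunoregulatory genes. The others hold markers of hepatocytes, neutrophils, macrophages and monocytes, T cells, NK and cytotoxic cells, B cells, dendritic cells with MHC class II, endothelial cells, mesenchymal and stellate cells, and erythroid cells with platelets. Lists were tested with camera (preset correlation 0.01, against all other genes of the fit, Benjamini-Hochberg over the lists of a comparison). Camera with an estimated correlation and fry were alternatives. A list score is the median, over the members, of each gene's value minus its mean over the arrays of the tissue.

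The rule for the genes named takes, for each comparison, genes past the threshold whose groups do not overlap, the 10 with the largest rise and the 10 with the largest fall. Where fewer than 5 pass in a direction, it adds the 5 with the smallest p in that direction among genes whose groups do not overlap, as values that did not pass. It also takes up to 4 members of each list with the smallest p, and the fixed panel Ifng, Tnf, Il6, Il1b, Il4, Il10, Il2, Ccl2, Cxcl10, Cxcl1, Saa1, Alb, Fasl, Il12b and Tgfb1 whatever its values. The comparison of tissues names list members plus the 5 largest changes in each direction. Genes outside the rule are marked where they are named.

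The first set of other settings held normexp background correction (offset 50) with the 75th percentile or with quantile normalization, quantile normalization of the processed signal, scaling to the median of probes above background on all arrays, no filter on dim probes, a filter to probes above background on every array, the slide as a fixed or random block, the arrays of the compared groups alone, eBayes with trend and robust, array weights, the mean of all probes of a gene, outlier spots kept, the series value table, a threshold of unadjusted p 0.05 with at least 2-fold, an adjusted p of 0.1, and leaving out each sample in turn. Other settings chosen after seeing the data were leaving out mice 10 and 13 together, the 5 h livers alone with array position or slide as a block, and the list tests of the 5 h livers alone.

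Each liver slide held 1 array of each of the 4 liver groups, and the 4 arrays of inflammatory cells shared a slide of their own. Deviations from the group means of liver arrays on the same slide correlated with a median r of 0.03, across genes, against -0.02 for arrays on other slides. In the liver fit the consensus correlation within slides was 0.07. Array positions differed between the 2 h groups, between the 5 h and 2 h livers and between the groups of inflammatory cells, so for these position and group cannot be told apart. The fits were tested on simulated data of the same size in which 200 genes changed. For a log2 change of 2, they found 80.6% of the changed genes in the 2 h comparison of 14580 genes, 83.6% in the 5 h comparison, 86.6% between times, 77.6% for the difference between schedules, and 47.8% among the 14182 genes of inflammatory cells. Of the 16233 genes of both tissues, they found 71.6% between tissues and 40.3% for the difference of effects. For a log2 change of 1 these shares were 46.3%, 44.8%, 47.8%, 11.9% and 3%, then 19.4% and 1.5%. Unchanged genes made up 7 of 155 calls at 2 h, 14 of 163 at 5 h and 6 of 161 between times. They made up 7 of 126 between schedules and 10 of 109 in inflammatory cells. Between tissues they were 7 of 125, and for the difference of effects 4 of 87. Of the 20 lists left without a shift, 1 was called between times and 0 in every other comparison. Simulated genes varied independently of each other, and these lists held random genes. The list counts therefore do not show how often camera wrongly calls a list of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.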

Results

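The arrays measured RNA of female C57Bl/6 mice, each injected with 300 µg of concanavalin A, a plant lectin that activates T cells and causes acute hepatitis. Stem cells grown from inguinal fat were given into the tail vein, 100000 per mouse, either together with concanavalin A or 3 h after it. Livers came from 4 groups of 3 mice: 2 h after concanavalin A alone, 2 h after concanavalin A with immediate stem cells, 5 h after concanavalin A alone, and 5 h after concanavalin A with stem cells at 3 h. Hepatic inflammatory cells at 5 h came from 2 groups of 2 samples, without stem cells and with stem cells at 3 h. The labels do not say whether each sample of inflammatory cells came from a separate mouse, so their p-values measure the spread between these samples. No mouse without concanavalin A was measured. Between 52.1% and 62.5% of the spots of an array lay well above background. All values are log2 signal relative to the array's 75th percentile.

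The livers of mice given concanavalin A alone were compared at 5 h and at 2 h, to follow the hepatitis without stem cells. Interferon-induced genes rose: of 26 measured genes of the type I interferon response, 18 rose and 0 fell (19 adjusted over the list alone), among them the antiviral enzymes Cmpk2 (by 2.20 ± 0.26, adjusted p = 0.0019) and Rsad2 (by 2.06 ± 0.28). Of 28 genes of the interferon-gamma response 8 rose (10 adjusted over the list alone), including the tryptophanyl-tRNA synthetase gene Wars by 2.09 ± 0.21, the immunoproteasome gene Psmb8 by 1.08 ± 0.17 and the inducible nitric oxide synthase gene Nos2 by 2.23 ± 0.51. Acute phase genes rose in 8 of 28 cases (12 adjusted over the list alone), with Apcs, serum amyloid P, up by 1.89 ± 0.32 and Il1r1, an interleukin 1 receptor, by 3.16 ± 0.48. A2m was at least 10.7-fold higher at 5 h (adjusted p = 0.0031). Neutrophil markers rose in 5 of 18 cases (12 adjusted over the list alone), and Chil3 rose by 2.52 ± 0.53. The neutrophil score at 2 h was -2.44 in mouse 13, against -0.31 and -0.28 in the other livers without stem cells. The heat shock and unfolded protein list had 6 of 21 members up (10 adjusted over the list alone): Hspa1a rose by 4.31 ± 0.81, Hspa1b by 3.14 ± 0.67 and the endoplasmic reticulum gene Creld2 by 1.83 ± 0.39.

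In the same comparison, markers of endothelial cells fell in 9 of 20 cases (10 adjusted over the list alone), with Gpr182 at -3.47 ± 0.45 and the VEGF receptor gene Kdr at -1.81 ± 0.27. B cell markers fell in 4 of 16 cases (10 adjusted over the list alone), among them Fcmr, a receptor for IgM, which fell by 2.21 ± 0.30, and Blnk, which fell by 1.13 ± 0.23. The circadian transcription factor gene Dbp fell by 5.28 ± 0.43, and the clock gene Per3 was at least 3.42-fold lower at 5 h (adjusted p = 0.000492). G6pc, whose enzyme releases glucose, fell by 5.29 ± 0.67, the glycogen-targeting phosphatase subunit gene Ppp1r3g fell by 5.39 ± 1.12, and the glycogen synthase gene Gys2 fell by 1.25 ± 0.21. The lectin gene Clec2h was at least 8.65-fold lower (adjusted p = 0.00233). Cpne8 rose by 3.57 ± 0.33. Single genes of other lists rose as well: the granzyme gene Gzmb by 2.20 ± 0.49, the cyclooxygenase gene Ptgs2 by 3.35 ± 0.79, the chemokine gene Ccl8 by 3.01 ± 0.61, the protease inhibitor gene Timp1 by 1.98 ± 0.32, the necroptosis gene Mlkl by 1.82 ± 0.37 and the ubiquitin-like gene Ubd by 3.50 ± 0.79.

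**Figure D1:**
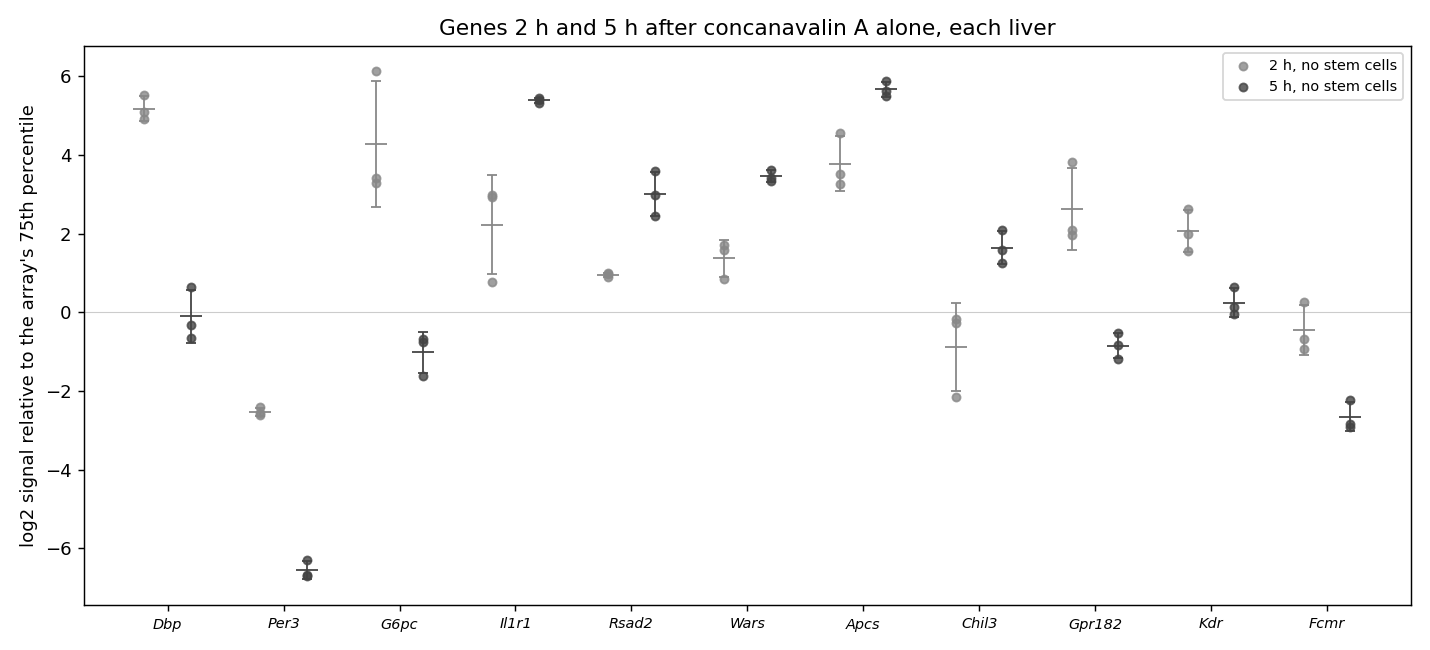
Each point is the log2 signal, relative to the array's 75th percentile, of 1 liver taken 2 h (light grey) or 5 h (dark grey) after concanavalin A alone; bars give the mean and SD of 3 livers. All 3 livers at 5 h lie below those at 2 h for Dbp, Per3, G6pc, Gpr182, Kdr and Fcmr, and above them for Il1r1, Rsad2, Wars, Apcs and Chil3.

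Of 14580 genes tested between these times, 938 rose and 1345 fell, and the 3 livers of each time did not overlap in 35.8% of genes, where chance gives 10%. Camera called 14 of the 22 lists. Those above the other genes had median log2 changes of 1.74 (interferon-gamma response), 1.44 (type I interferon), 1.87 (neutrophil markers), 1.06 (acute phase), 1.15 (chemokines), 0.91 (myeloid cytokines), 0.83 (heat shock), 0.64 (cell death), 0.64 (stromal immunoregulatory genes), 0.52 (immediate early genes) and 0.34 (NK and cytotoxic cells). Those below had medians of -0.73 (B cells), -0.59 (endothelial cells) and -0.31 (hepatic metabolism). No call of these 14 held with an estimated correlation, where the adjusted p lay between 0.331 and 0.631. Fry called 11 lists, 10 of them among these 14. The other 8 lists had medians of -0.32 (dendritic cells and MHC class II), -0.24 (macrophages), -0.21 (mesenchymal cells), -0.21 (cell cycle), -0.09 (T cells), 0.03 (hepatocytes), 0.06 (T cell cytokines, with a mean of -0.07) and 0.17 (erythroid cells). With the slide as a block 2262 genes passed, and Dbp changed by -5.55, -4.43 and -5.84 within the 3 slides. Mouse 13, which stood apart among the 2 h livers, lay on slide 3: within slides 1, 2 and 3 the median was 0.92, 0.75 and 3.77 for the interferon-gamma response, 1.12, 0.61 and 2.07 for type I interferon and 0.93, 1.18 and 3.35 for neutrophil markers. It was 0.67, 0.47 and 1.79 for acute phase, 0.11, 0.32 and 2.83 for chemokines and 0.08, 0.38 and 2.84 for myeloid cytokines. Without mouse 13, camera called 9 lists, 6 above and 3 below. The count was 1373 without mouse 13 of the 2 h livers, 903 without mouse 4 and 888 without mouse 6 of the 5 h livers. It was 486 when only these 6 arrays were fitted, 1327 with no filter on dim probes and 287 after normexp correction with the 75th percentile.

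Immediate stem cells were compared with none in the livers at 2 h, which addresses whether cells given with concanavalin A alter the early liver response. Ptcra, the pre-T cell receptor alpha chain, was at least 1.695-fold higher with stem cells (adjusted p = 0.00404; probe on chromosome 17, 46219187 to 46219247, build mm8). Tnfrsf23, a decoy receptor of the TNF family, was at least 1.337-fold lower (adjusted p = 0.00404), with 2 of 3 control livers well above background. D330040H18Rik fell by 1.53 ± 0.16 (adjusted p = 0.00742). Trim6, a ubiquitin ligase of the interferon response, fell by 2.40 ± 0.30 (adjusted p = 0.0322) by its brightest probe, and 3 of its 4 probes went the same way. Genes of red blood cells lay lower without passing the test: Hba-a1 at -1.28 ± 0.18 (adjusted p = 0.0825), the haem synthesis gene Alas2 at -0.94 ± 0.20 and Hbb-bt at -0.94 ± 0.25. The class II transactivator gene Ciita had -1.23 ± 0.19 (adjusted p = 0.0981), H2-Ab1 had -0.56 ± 0.15 and Itgax had -0.84 ± 0.20, where 1 of 2 probes had this sign. The interleukin 10 gene Il10 had 1.59 ± 0.26 (adjusted p = 0.139), Cyp1a1 was at least 2.4-fold higher (adjusted p = 0.0825) and Postn had -0.80 ± 0.13, without passing. The interferon-induced genes Ifit2 (-1.88 ± 0.46), Mx1 (at least 1.76-fold lower) and Isg20 (-1.01 ± 0.26) did not pass (adjusted p = 0.57 to 0.581). The hepatitis cytokines gave Ifng -0.18 ± 0.81, Tnf -0.30 ± 0.90, Cxcl10 0.04 ± 1.87 and Il6 1.75 ± 1.33, none of which passed.

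Among the lists in these 2 h livers, type I interferon genes had the smallest camera p, with a median of -0.77, 24 of 26 members below 0 and 8 lower when adjusted over the list alone (camera adjusted p = 2.55e-16, adjusted p = 0.125 with an estimated correlation). The interferon-gamma list had a median of -1.04 (25 of 28 below 0, camera adjusted p = 5.19e-10, adjusted p = 0.457 with an estimated correlation). Dendritic cell and MHC class II genes had a median of -0.37 and erythroid and platelet markers one of -0.47, each with adjusted p = 0.0644 with an estimated correlation. Camera placed 10 lists below the other genes and 0 above, and neither the estimated correlation nor fry called any. Within slides 1, 2 and 3 the interferon-gamma median was -1.47, -3.24 and 1.55. A treated and an untreated liver stood apart from the other 2 h livers: the chemokine score was -1.93 in mouse 10 with stem cells and -2.31 in mouse 13 without, against -0.36 to 0.49 in the other 4, and their interferon-gamma scores were -2.64 and -2.77, against -1.14 to 0.63.

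Of 14580 genes, 1 rose and 3 fell in the 2 h livers by limma, 817 had an unadjusted p under 0.05, and the groups did not overlap in 8.2% of genes, where chance gives 10%. The count was 0 without mouse 8 or mouse 10 of the treated livers, 2 without mouse 9, 2 without mouse 12 and 481 without mouse 13 of the controls, 446 without mice 10 and 13. It was 3 with the slide as a block, 295 with array weights and 0 with these 6 arrays alone. After normexp correction with the 75th percentile no gene passed, and Tnfrsf23 (0.49) and D330040H18Rik (0.02) turned positive, as did Mx1 (0.37), while Cxcl10 turned negative (-0.48).

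**Figure D2:**
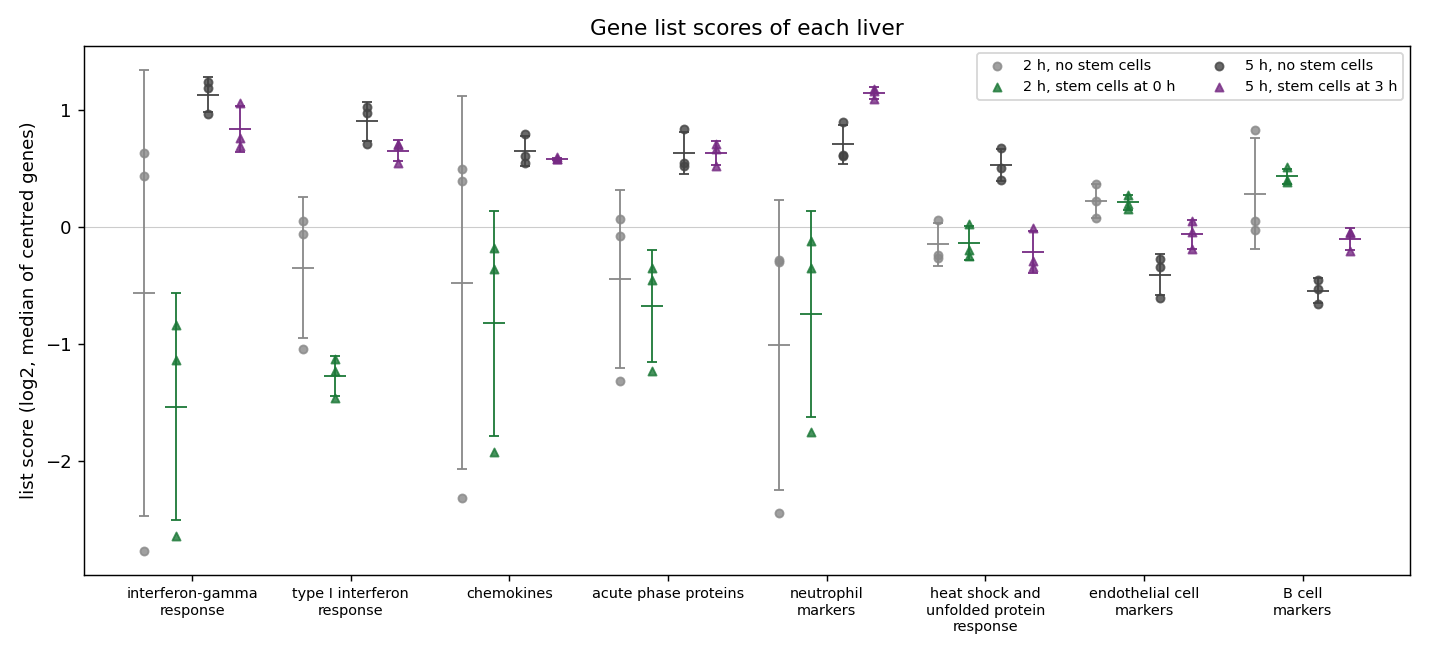
Each point is the score of a gene list in 1 liver, the median over its members of log2 signal minus the gene's mean over the 12 livers; bars give the mean and SD of 3 livers. At 2 h, 1 liver of each group lies far below the others for the interferon-gamma response, chemokines and neutrophil markers, while the heat shock list lies lower in all 3 livers with stem cells at 3 h than in the 3 livers at 5 h without.

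Stem cells given at 3 h were compared with none in the livers at 5 h, which addresses treatment after the hepatitis has begun. Gadd45a, a growth arrest and DNA damage gene, rose by 1.64 ± 0.19 (3.11-fold, adjusted p = 0.0199; probe on chromosome 6, 66964960 to 66965019, build mm8). Reg3g, an antimicrobial lectin, was at least 1.606-fold lower (adjusted p = 0.0199) and 9130004C02Rik at least 1.215-fold lower (adjusted p = 0.0199). Gimap5, a GTPase gene of lymphocytes, rose by 1.90 ± 0.17 (adjusted p = 0.00489) by its brightest probe, while its other probe gave -0.04. Ptcra had a log2 change of 2.04 ± 0.24 (adjusted p = 0.0199), with all 6 livers below background, so that no fold is given. Erv3 (at least 6.25-fold higher, adjusted p = 0.123), the pyruvate dehydrogenase kinase gene Pdk4 (2.64 ± 0.45, adjusted p = 0.125), the DNA polymerase gene Polk (-1.83 ± 0.25, adjusted p = 0.0535) and Khdc4 (-1.53 ± 0.22, adjusted p = 0.0656) did not pass.

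Heat shock and unfolded protein genes formed the list farthest from the other genes in the 5 h livers. Their median was -0.53, with 18 of 21 members below 0 and 0 past the threshold over all genes. Adjusted over the list alone, 7 fell. The largest were the inducible Hsp70 genes Hspa1a (-3.54 ± 0.81) and Hspa1b (-2.95 ± 0.67), then Creld2 (-1.62 ± 0.39) and the stress transcription factor gene Ddit3 (-1.48 ± 0.42). The list's adjusted p was 9.97e-08 by camera, 0.0352 by fry and 0.0729 with an estimated correlation, and its median was -0.87, -0.31 and -0.51 within the 3 slides. The list score was -0.22 ± 0.18 with stem cells and 0.53 ± 0.14 without (SD, n = 3), exact permutation p = 0.1, the smallest that 3 against 3 allows. Interferon-gamma genes had a median of -0.42 and type I interferon genes one of -0.18, with Zbp1 at -1.71 ± 0.40, Wars at -0.83 ± 0.21 and Ciita at -0.76 ± 0.19 (adjusted p = 0.805 with an estimated correlation for both lists). Markers of macrophages (0.39), endothelial cells (0.41) and B cells (0.49) lay above the other genes by camera, each with adjusted p = 0.805 with an estimated correlation. Their members included Clec4f of Kupffer cells at 0.38 ± 0.15, Kdr at 0.85 ± 0.27, Clec4g at 0.70 ± 0.22, Cd37 at 1.5 ± 0.44 and Vpreb3 at 0.79 ± 0.24. The monocyte receptor gene Ccr2 was at least 1.32-fold higher (adjusted p = 0.255), with 1 of 6 livers above background, and did not pass. Ifng had 0.53 ± 0.81, Tnf -1.12 ± 0.90, Cxcl10 0.45 ± 1.87 and Il6 0.85 ± 1.33. Each error draws on the spread pooled over all 12 livers, mice 10 and 13 included, so it equals the error at 2 h. It does not measure the spread among the 5 h livers alone. Chemokine scores ran from 0.54 to 0.80 in the 5 h livers and from -2.31 to 0.49 in the 2 h livers.

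Of 14580 genes, 3 rose and 2 fell in the 5 h livers by limma (Ptcra, below background in all 6, is among the 3), 1806 had an unadjusted p under 0.05, and the groups did not overlap in 22.2% of genes, where chance gives 10%. The count was 0 without mouse 1 or mouse 3 and 27 without mouse 2 of the treated livers, 2 without mouse 4, 2 without mouse 5 and 1 without mouse 6 of the controls. It was 25 with these 6 arrays alone (3 of the 5 genes among them), 4 with the slide as a block, 139 with array weights, 0 after normexp correction with the 75th percentile, and 0 with the 6 arrays alone and array position or slide as a block. With the 6 arrays alone Gimap5 had -0.04, the value of its other probe.

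**Figure D3:**
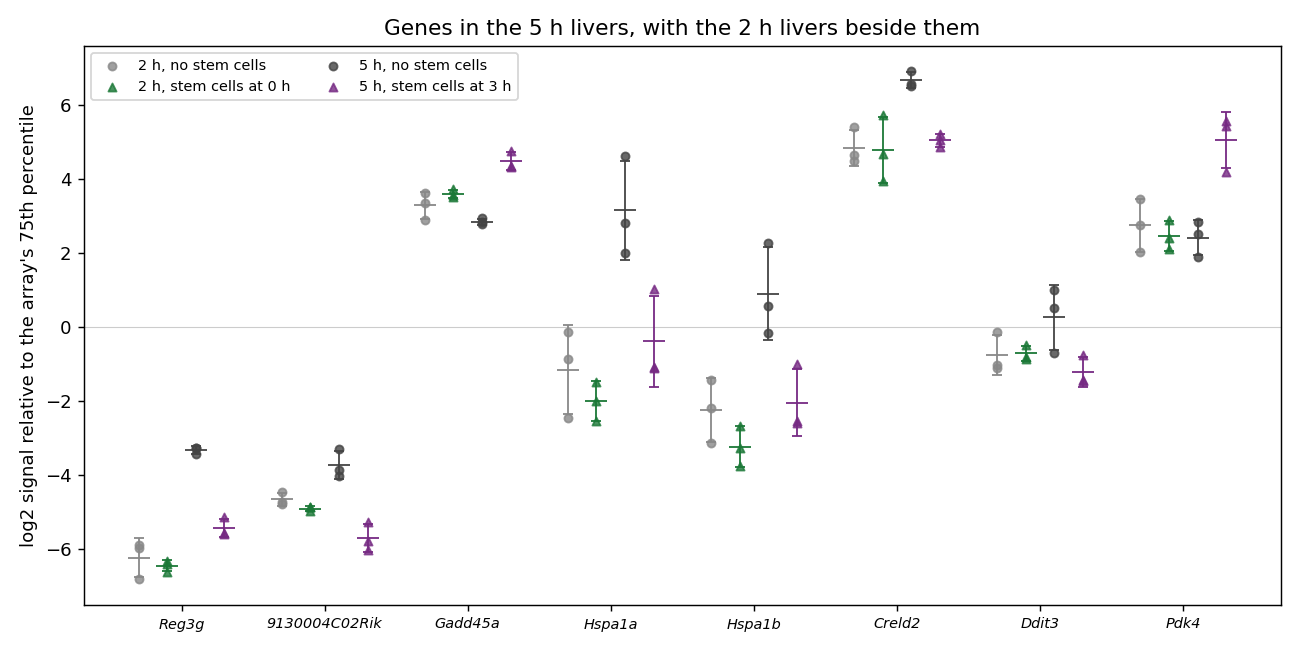
Each point is the log2 signal, relative to the array's 75th percentile, of 1 liver, in the 4 liver groups; bars give the mean and SD of 3 livers. At 5 h, Gadd45a and Pdk4 are higher and Reg3g, 9130004C02Rik, Hspa1a, Hspa1b, Creld2 and Ddit3 lower in all 3 livers with stem cells at 3 h than in the 3 without; of these genes Gadd45a, Reg3g and 9130004C02Rik passed the test.

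The effect of stem cells was then compared between the schedules, as the difference of the 5 h and the 2 h effects in the liver fit. Gimap5 differed by 2.01 ± 0.23 (adjusted p = 0.0372) by its brightest probe, whose other probe gave -0.04 for the 5 h effect. With the mean of both probes the difference in Gimap5 was 1.49 and did not pass (adjusted p = 0.851, over a range of 0.00413 to 1 across the alternatives). Tnfrsf23 passed as well, with a fitted difference of 3.12 ± 0.33 (adjusted p = 0.0331), but 1 of its 4 groups lay below background, and with dim signals raised to the floor its difference was 1.14. Reg3g did not pass (adjusted p = 0.359), with 3 of 4 groups below background. The heat shock list had a median difference of -0.60 (camera adjusted p = 6.38e-06, adjusted p = 0.0597 with an estimated correlation), erythroid markers one of 0.80 and dendritic cell genes one of 0.46 (adjusted p = 0.0597 with an estimated correlation for both). Of 14580 genes these 2 passed by limma and 679 had an unadjusted p under 0.05. The count was 0 without any 1 of 10 of the 12 mice, 1 without mouse 4, 16 without mouse 13 and 0 with the slide as a block, and Tnfrsf23 turned negative (-0.14) after normexp correction with the 75th percentile.

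In hepatic inflammatory cells at 5 h, stem cells given at 3 h were compared with none, 2 samples each. Il3, a blood cell growth factor made by activated T cells, was at least 31.96-fold lower with stem cells (adjusted p = 0.0202; probe on chromosome 11, 54108918 to 54108977, build mm8), and the chemokine gene Ccl1 of activated T cells fell by 5.88 ± 0.40 (59.0-fold, adjusted p = 0.0327). Other cytokine and activation genes of T cells lay lower without passing: Ifng at -2.95 ± 0.37 (adjusted p = 0.0911), the interleukin 2 receptor gene Il2ra at -4.27 ± 0.55 (adjusted p = 0.0962), Tnfrsf9 at -3.14 ± 0.55, Il2 at -3.05 ± 0.69, Il4 at -3.73 ± 0.82 and Tnf at -1.86 ± 0.49. In that list 24 of 25 genes lay below 0, the median was -1.86, and 18 fell when adjusted over the list alone (camera adjusted p = 3.67e-15, adjusted p = 0.307 with an estimated correlation, fry adjusted p = 0.0669). The interferon-gamma list had a median of -1.63, with 25 of 27 genes below 0 and 17 lower when adjusted over the list alone (camera adjusted p = 1.95e-13, adjusted p = 0.539 with an estimated correlation). Its members included the GTPase genes Irgm2 (-3.92 ± 0.35, adjusted p = 0.0712) and Tgtp1 (-3.12 ± 0.45) and the chemokine genes Cxcl11 (-4.18 ± 0.50) and Cxcl10 (-2.73 ± 0.51). The monocyte chemokine genes Ccl7 (-3.48 ± 0.36) and Ccl2 (-2.48 ± 0.37), Il6 (-2.92 ± 0.42) and the apoptosis inhibitor gene Cflar (-2.27 ± 0.46) lay lower too. Of the fixed panel, Il1b, Il12b, Tgfb1, Saa1 and Alb overlapped between the groups. Il1b had 2.36 and 2.53 with stem cells against 1.72 and 4.86 without, and Il12b -2.56 and -1.21 against -3.59 and -2.08. The checkpoint receptor gene Pdcd1 had -4.11 ± 0.37 and the recombinase gene Rag1 was at least 6.62-fold lower, without passing (adjusted p = 0.0712 for both).

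Markers of neutrophils and macrophages had medians above 0 in these cells with stem cells, with adjusted p = 0.494 and 0.702 with an estimated correlation. The neutrophil list had a median of 0.82 (15 of 19 above 0, 6 higher when adjusted over the list alone), with the gelatinase gene Mmp9 at 2.66 ± 0.36, S100a8 at 1.98 ± 0.39 and S100a9 at 1.89 ± 0.37. The macrophage list had a median of 0.80 (18 of 21 above 0, 2 higher and 1 lower when adjusted over the list alone), with the scavenger receptor gene Marco at 2.38 ± 0.38 and the F4/80 gene Adgre1 at 1.63 ± 0.38. Msr1, another scavenger receptor gene, had -1.34 ± 0.34. Over all genes none of Mmp9, S100a8, S100a9, Marco, Adgre1 and Msr1 passed. The macrophage list score was 0.39 and 0.49 with stem cells, 0.13 in untreated sample 985 and -0.98 in untreated sample 983. Without sample 983, 6 lists passed, 1 above and 5 below the other genes. T cell markers had a median of -0.32, with Zap70 at -1.32 ± 0.37 and Tcf7 at 1.19 ± 0.38. Hepatocyte markers had a median of 0.95, with 17 of 17 members above 0 (camera adjusted p = 0.00311, adjusted p = 0.702 with an estimated correlation). Alb had 1.04 ± 0.72 and Cps1 2.81 ± 0.74, and the hepatocyte score was 0.50 ± 0.90 with stem cells and -0.58 ± 1.11 without (SD, n = 2). The groups overlapped in this score: treated sample 987 had -0.14, below 0.21 in untreated sample 985, while untreated sample 983 had -1.37. The brown fat gene Ucp1 was at least 2.8-fold higher and did not pass (adjusted p = 0.0712).

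Of 14182 genes, 0 rose and 2 fell in inflammatory cells by limma, 2546 had an unadjusted p under 0.05, and the groups did not overlap in 52.5% of genes, where chance gives 33.3%. Camera called 10 lists, 5 above and 5 below the other genes, and none held with an estimated correlation or by fry. The count was 0 without sample 983, 987 or 989 and 2138 without the untreated sample 985, 961 after normexp correction with the 75th percentile (247 higher, 714 lower) and 0 after normexp with quantile normalization.

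**Figure D4:**
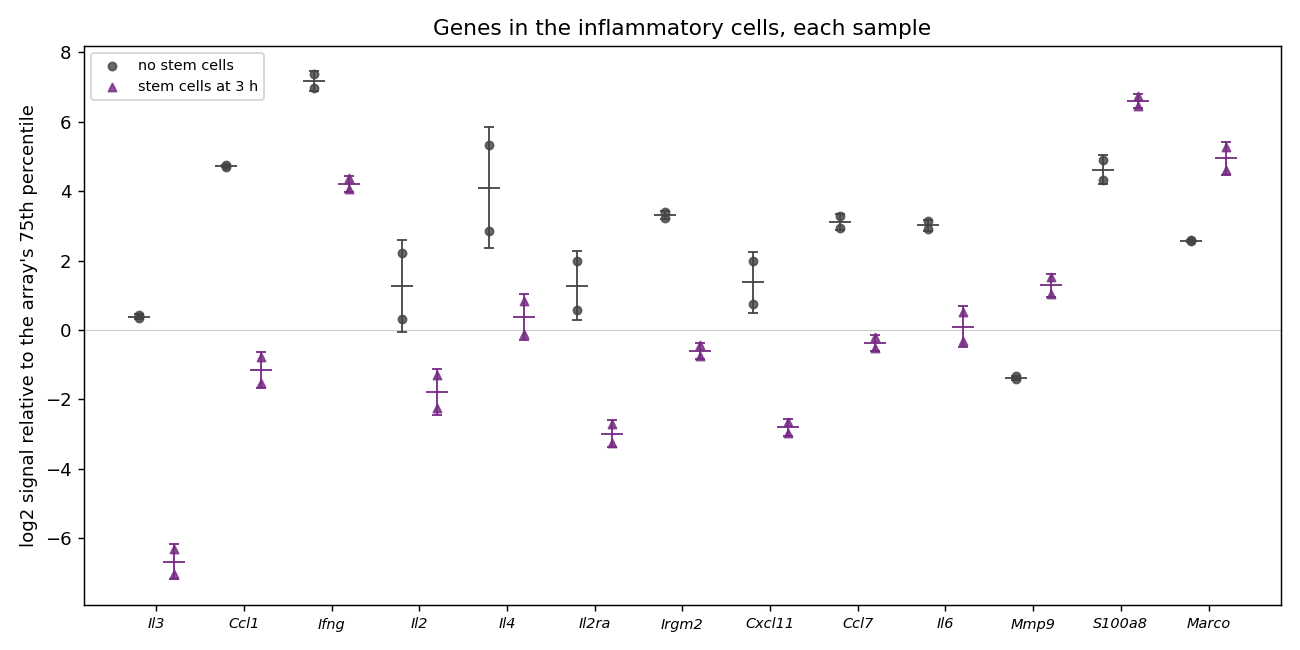
Each point is the log2 signal, relative to the array's 75th percentile, of 1 sample of hepatic inflammatory cells at 5 h, without (circles) or with (triangles) stem cells at 3 h; bars give the mean and SD of 2 samples. Both samples with stem cells lie below both without for Il3, Ccl1, Ifng, Il2, Il4, Il2ra, Irgm2, Cxcl11, Ccl7 and Il6, and above them for Mmp9, S100a8 and Marco; Il3 and Ccl1 passed the test.

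Inflammatory cells and livers without stem cells were compared at 5 h to show what the cell preparation holds. Lymphocyte and dendritic cell markers were higher in the cells: 18 of 18 B cell markers rose (Ms4a1, the CD20 gene, by 7.41 ± 0.37), 17 of 19 T cell markers (Cd3d by 5.69 ± 0.22), 18 of 19 NK and cytotoxic markers (Klrb1c by 6.26 ± 0.26) and 18 of 19 dendritic cell and MHC class II genes (Cd74 by 4.51 ± 0.25). T cell cytokine genes rose in 22 of 25 cases, with the death ligand gene Fasl up by 5.80 ± 0.41 and Il3 at least 25.9-fold higher. P2ry10 was at least 147.7-fold and H2-Ob at least 67.19-fold higher. Of 19 neutrophil markers 6 rose, with Mpo up by 5.80 ± 0.51, and 1 fell, and of 21 macrophage markers 8 rose and 4 fell, with a median of 0.03. Genes of hepatocytes were lower: 17 of 17 markers fell, with the urea cycle gene Cps1 at -11.54 ± 0.46, the transferrin gene Trf at -6.52 ± 0.20 and the apolipoprotein gene Apoa1 at -6.30 ± 0.23, and Gulo fell by 9.74 ± 0.54. Genes of hepatic metabolism (27 of 29), acute phase proteins (26 of 28) and mesenchymal cells (20 of 23) fell too, and 18 of 20 cell cycle genes rose. With an estimated correlation the NK and cytotoxic list held (adjusted p = 0.0101), neutrophil and macrophage markers had adjusted p = 0.715, and the other lists named here had adjusted p = 0.0649 to 0.206. Camera with the preset correlation did not call neutrophil or macrophage markers (adjusted p = 0.0947 and 0.228). Of 16233 genes, 4749 were higher and 5142 lower. Livers and cells lay on different slides, so tissue and slide cannot be told apart.

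The effect of stem cells at 3 h was compared between inflammatory cells and liver in the same fit. T cell genes passed with a lower effect in the cells: Il2ra at -4.81 ± 1.04 and the costimulator gene Icos at -2.10 ± 0.39, both measured in all 4 groups. Il3 had a fitted difference of -7.56 ± 0.49 (adjusted p = 2.38e-05), Il21 of -3.66 ± 0.71 and Il17a of -3.24 ± 0.69. These had 3, 2 and 2 groups below background, and with dim signals raised to the floor the differences were -5.29, -2.78 and -3.08. In the T cell cytokine list 24 of 25 genes lay below 0, with a median of -1.99, and 5 passed (10 adjusted over the list alone; camera adjusted p = 1.91e-08, fry adjusted p = 0.00686, adjusted p = 0.3 with an estimated correlation). Irgm2 differed by -3.50 ± 0.78 and the replication clamp gene Pcna by -1.06 ± 0.24, and Ttc39a (4.08 ± 0.69) the other way. Rag1 (-4.77 ± 0.44) and Ucp1 (3.38 ± 0.46) passed with 3 of 4 groups below background, and with dim signals raised to the floor they had -3.02 and 1.19. Of 16233 genes 365 passed, 81 with a higher and 284 with a lower effect in the cells. The count was 189 with the slide as a block, 197 with these 10 arrays alone, 3 after normexp correction with the 75th percentile (0 higher, 3 lower), 1065 with quantile normalization after normexp (475 higher, 590 lower), 573 with quantile normalization alone (191 higher, 382 lower), 2365 without sample 985, 86 without sample 987 and 114 without sample 983, where the lone sample left is assumed to vary like the other groups. It was 133, 203 and 116 without mouse 1, 2 or 3 and 177, 161 and 129 without mouse 4, 5 or 6.

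The effects of stem cells were set side by side across genes, which are not independent replicates. The 2 h and 5 h liver effects correlated with Pearson's r of 0.43 and Spearman's rho of 0.39 over 14580 genes, a value that 7 of 100 relabelings of the mice reached. The effects at 5 h in liver and inflammatory cells correlated with r of 0.29 and rho of 0.35 over 13140 genes, which 2 of 100 relabelings reached. Those of 2 h livers and inflammatory cells correlated with r of 0.24 and rho of 0.24, which 15 of 100 reached. The relabelings were counted by the size of r with either sign, and the real labeling was not kept out of the draw. For liver and cells at 5 h the highest r drawn was 0.294, the real value, and the lowest was -0.247. The 2 that reached it may therefore be the real labeling and the one with all groups exchanged, so their share says little about chance. These 3 pairs share no control samples.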

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

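The tests of explanations in this part were chosen after the result was seen, except the count of other splits of the mice. The results by limma, camera and fry, the mean of probes and the slide as a block were planned. The difference between the stem cell effects in the 5 h and 2 h livers passed for 2 genes by limma, Tnfrsf23 (3.12) and Gimap5 (2.01), and for 10 gene lists by camera, of which 0 held with an estimated correlation and 2 passed by fry. With signals below background raised to the floor, the difference for Tnfrsf23 was 1.14. The Gimap5 value rests on its brightest probe: its other probe gave -0.04 for the 5 h effect, and with the mean of both probes the difference was 1.49 (adjusted p = 0.851, over a range of 0.00413 to 1 across the alternatives). Of 100 splits of the mice within the times, 3 gave at least 2 genes, the real one included, a share under 0.05. For so small a count this share does not exclude chance. The highest other split gave 10 genes, several times the real count. Whether a structure of the samples lies behind that split was not tested. With the slide as a block the real count was 0.

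The difference between the effects of stem cells at 3 h in inflammatory cells and in liver passed for 365 genes. Among them were Il3 (-7.56), Il2ra (-4.81), Rag1 (-4.77), Il21 (-3.66), Irgm2 (-3.5), Il17a (-3.24), Icos (-2.1) and Pcna (-1.06), which had the lower effect in the cells, and Ttc39a (4.08) and Ucp1 (3.38), which had the higher. With signals below the floor raised to it these values were -5.29 for Il3, -3.02 for Rag1, -2.78 for Il21, -3.08 for Il17a, 3.48 for Ttc39a and 1.19 for Ucp1.

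T cell cytokine genes lay lower in the inflammatory cells of stem cell treated mice, with a median of -1.86. Fewer T cells among the cells would lower T cell markers alike, but their median lay 1.537 above that of the cytokine genes. This gap exceeded the interquartile range of the markers (0.676). T cell markers (-0.322) and NK and cytotoxic markers (-0.297) did lie below 0 by more than their bounds of 0.155 and 0.187. A bound is the interquartile range over the square root of the number of genes, so it measures spread across genes and not between samples. The T cell marker scores overlapped between the groups, with -0.519 and 0.297 with stem cells against -0.006 and 0.222 without. B cell (0.581) and macrophage markers (0.801) lay above 0. The B cell scores overlapped as well, with 0.281 and 0.310 with stem cells against -0.779 in sample 983 and 0.337 in sample 985. By the gap between the medians, an equal loss of all T cells is argued against as the whole source, while fewer T cells as a part of it stays open. Dilution of all leukocyte RNA by hepatocyte RNA would lower every leukocyte list, but neutrophil markers had a median of 0.824, above 0 by more than its bound of 0.287, although hepatocyte markers lay higher too. Array position stays open, since 0 positions held arrays of both groups and position and treatment cannot be told apart. The stem cell treatment itself is the biological explanation the design names and stays open, as does a change in the state or mixture of the cells.

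Mouse 10 with immediate stem cells and mouse 13 without stood apart from the other 4 livers at 2 h, and their values correlated with each other at r = 0.984 across genes. Dim arrays would have fewer spots above background than the others. Mouse 10 had 57.91%, inside the range of 56.5% to 62.5% of the other 4, while mouse 13 had 54.2%, below that range. Mouse 13 also had 100 outlier spots, the most of the 16 arrays, so a poor array stays open for mouse 13. A swap with a 5 h liver would leave a 2 h liver among the 5 h ones, but all 6 arrays at 5 h had their highest correlation with another 5 h array. A swap between the 2 h groups was not tested. Untreated mouse 13 correlated at 0.961, 0.969 and 0.984 with treated mice 8, 9 and 10, and at 0.945 and 0.951 with untreated mice 11 and 12. Little or no response to concanavalin A in these mice may account for the pattern: 3 lists (chemokines, T cell cytokines, myeloid cytokines) lay lower in both than in the other 4, but the mice were noticed on such lists and no mouse without concanavalin A was measured, so this stays open.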

How the results depend on the processing

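Leaving out mice 10 and 13 together, the fits of the 5 h livers alone with a block and the list tests of the 5 h livers alone were chosen after seeing the data; the other alternatives were planned. The cause of each change was not tested, unless the construction shows it. Signal over background limits what can be said of dim genes such as Ptcra, which was below background in all 5 h livers compared. Across the single genes named and the gene lists called by camera, 2875 alternatives kept direction and side of the threshold. Another 108 moved past it, 351 fell short of it and 27 reversed. Those that kept both include the series value table, which repeats the main fit. Of the counts, 143 stayed within 1.5 times and 102 did not. The count between tissues stayed within 1.5 times of 9891 in all alternatives run (7118 to 10807), and 9009 to 9404 without single samples. The correlations of the 5 h liver effects with the 2 h liver effects and with those of inflammatory cells kept their sign in the alternatives run. No spread was computed for them.

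For the 2 h livers (4 genes) the count was 0 with normexp and quantile normalization, 0 with normexp and the 75th percentile, 2 with probes above background on every array, 0 with only the compared arrays, 295 with array weights, 217 with unadjusted p 0.05 and 2-fold, 8 at adjusted p 0.1, 446 without mice 10 and 13, and 0 to 481 without single mice. Cxcl10 reversed to -0.007 (normexp and quantile), -0.476 (normexp and the 75th percentile), -0.006 (quantile), -0.664 (array weights), -0.705 (without mice 10 and 13), and ran from -2.416 to 1.75 without single mice. With normexp and the 75th percentile Tnfrsf23 gave 0.494, D330040H18Rik 0.022 and Mx1 0.37. Without single mice Ifng ran from -1.254 to 0.665, Tnf from -1.486 to 0.456 and Il6 from -0.19 to 2.926, with signs on both sides of 0. Of 10 lists 0 held with an estimated correlation and 0 by fry, and 8 to 13 passed without single mice. Without mouse 10 these were 2 above and 6 below the other genes, with 5 of the 10 among them, and without mouse 11 they were 1 above and 7 below.

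For the 5 h livers (5 genes) the count was 1 with normexp and quantile normalization, 0 with normexp and the 75th percentile, 2 with probes above background on every array, 8 with the slide as a random block, 25 with only the compared arrays, 2 with trend and robust, 139 with array weights, 441 with unadjusted p 0.05 and 2-fold, 9 at adjusted p 0.1, 45 without mice 10 and 13, 0 with the compared arrays and position as a block, 0 with slide as a block, and 0 to 27 without single mice. Gimap5 reversed to -0.059 (normexp and quantile), -0.077 (normexp and the 75th percentile), -0.042 (only the compared arrays, without mice 10 and 13, and with slide as a block), -0.041 (position as a block), and ran from -0.122 to 1.924 without single mice. Of 6 lists 0 held with an estimated correlation and 1 by fry, and 4 to 7 passed without single mice.

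For inflammatory cells (2 genes) the count was 0 with normexp and quantile normalization, 961 with normexp and the 75th percentile, 1 with quantile normalization, 24 with no filter on dim probes, 4 with probes above background on every array, 4 with trend and robust, 2231 with unadjusted p 0.05 and 2-fold, 29 at adjusted p 0.1, and 0 to 2138 without single samples, where the lone sample left is assumed to vary like the others. Of 10 lists 0 held with an estimated correlation and 0 by fry, and 6 to 14 passed without single samples. Between 5 h and 2 h (2283 genes) it was 287 with normexp and the 75th percentile, 1327 with no filter on dim probes, 486 with only the compared arrays, 3597 at adjusted p 0.1 and 888 to 2373 without single mice; of 14 lists 0 held with an estimated correlation, and 9 to 14 passed without single mice.

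For the difference between schedules (2 genes) the count was 0 with normexp and either scaling, 0 with no filter on dim probes, 1 with probes above background on every array, 0 with the slide as a fixed block, 1 with trend and robust, 1 with the mean of probes, 277 with unadjusted p 0.05 and 2-fold, 74 without mice 10 and 13, and 0 to 16 without single mice. Tnfrsf23 reversed to -0.142 with normexp and the 75th percentile. Of 10 lists 0 held with an estimated correlation and 2 by fry, and 9 to 15 passed without single mice. For the difference between cells and liver (365 genes) it was 1065 with normexp and quantile normalization, 3 with normexp and the 75th percentile, 573 with quantile normalization, 215 with no filter, 674 with probes above background on every array, 189 with the slide as a fixed block, 197 with only the compared arrays, 148 with array weights, 240 with the mean of probes, 1926 with unadjusted p 0.05 and 2-fold, 881 at adjusted p 0.1, and 86 to 2365 without single samples. The median of all genes shifted by 0.142 (inflammatory cells, normexp and the 75th percentile), 0.126 and -0.276 (between tissues, quantile normalization and no filter) and 0.278 (difference between cells and liver, normexp and the 75th percentile).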

Other observations

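The tests of clock genes across slides in this part were chosen after the result was seen, while the counts of other splits were planned. The prediction for the time of day was written beforehand, but Dbp and Per3 in its gene set were named for their fall in these data. The clock genes named here lie outside the rule for named genes and were chosen after their values were seen, apart from Dbp and Per3. In livers with stem cells, which the report compares only with livers without them, the 5 h group was also lower than the 2 h group for Dbp (-6.67), Tef (-3.60), Nr1d2 (-1.93) and Hlf (-1.62), and higher for Nfil3 (2.30), while Arntl had 2.02 and did not pass. Without stem cells the values were -2.55 for Tef, -2.03 for Hlf, -1.06 for Nr1d2, and 1.17 for Nfil3, while Arntl had 1.93 and did not pass. Nr1d1 (-0.17) and Clock (0.26) did not pass either. Per3, Npas2 and Cry1 lay below background in at least 1 group and have only bounds. Per1 had 0.26 without and -1.83 with stem cells.

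The time of day of the harvest is a candidate explanation for the lower clock genes at 5 h, since a set of 10 genes that fall together in the day and 5 of the opposite phase would then move in both treatments. The median of the 10 genes differed by -1.47 without and by -2.025 with stem cells, and that of the 5 genes by 0.975 and 1.954 (exact permutation p = 0.1 for each, the smallest that 3 livers against 3 allow). Each slide held an array of each liver group, so a shift of a whole slide cancels in this difference and cannot be its source. Within the 3 slides the 10 genes had medians of -0.905, -1.32 and -1.86. Array position differed between the 5 h and 2 h livers and cannot be told apart from time here. The time after concanavalin A is the biological explanation the design names, and it stays open, since the harvest times of day are not given. It could move these genes in both treatments as well, so the values favour neither explanation.

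For the 3 comparisons of 3 livers against 3, the 10 splits of the mice are too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many genes: 4 genes at 2 h, 5 genes at 5 h and 2283 genes between the times, where the highest other split gave 0.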
